A study of Homo sapiens with 5 samples.

How the data were processed

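RNA sequencing was measured in 5 libraries of WI38 human lung fibroblasts transduced with lentiviral vectors. The deposited table holds raw read counts per gene symbol, with 1 column for each library and no replicates pooled. Per the submitters' processing notes, STAR 2.5 and the hg19 genome build were used. The counting program, the gene annotation, the strand setting and the library kit are not given in the sources used here, so antisense and overlapping genes cannot be separated, and genes with near-identical copies such as histones, keratins and the pseudogene RPLP0P2 are uncertain. The reference given was of another build than the authors' hg19, so no coordinates are printed, and the RefSeq table was used for older gene symbols only.

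Groups were taken from the labels. The library labelled control shRNA, the empty vector library and the KLF9 cDNA library are 1 each. The KLF9 shRNA group has 2 libraries, each with an independent hairpin, named hairpin 1 and hairpin 2 here. No label says that any library came from a separate culture, and the only spread between libraries of 1 group is therefore that between 2 hairpins. It includes differences between the hairpins themselves, and the single control libraries were assumed to vary alike. The hairpin libraries were not duplicates of each other (chi-square per degree of freedom 77.4).

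Depth was 22859081 to 27241974 counts per library, over 26363 genes, of which 6266 had no count in any library. Counts were scaled with edgeR's TMM factors, and fold changes are differences of log2 CPM (counts relative to the scaled library total) with a prior count of 2. Confidence intervals are 95% intervals, exact Poisson for a CPM value and exact conditional binomial for a ratio of 2 libraries. They cover counting error only, since reads without molecular identifiers are not independent molecules. The intervals of list medians in the closing section run over the member genes of a list instead.

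The knockdown was tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test on 15177 genes kept by its expression filter with a minimum count of 10, in 4 groups over all 5 libraries. There was 1 residual degree of freedom, 6.36 prior degrees of freedom and a common dispersion of 0.0925, and p-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. KLF9 cDNA against empty vector is 1 library against 1, so no test was made as the main result, and the values compare those libraries, not the conditions. Beside the test, a rule of size counted genes with at least 2-fold change and a mean of at least 1 CPM over the libraries compared. For the knockdown both hairpins had to pass in the same direction.

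There were 27 gene lists with 560 symbols, all matched in the table, 1 of them through an older symbol. They cover ER calcium handling, XBP1 and ATF6 chaperones, ER-associated degradation (ERAD) and translocation, PERK, ATF4 and CHOP targets, apoptosis, NRF2, glucocorticoid and circadian genes, the KLF and SP family, S phase, G2 and M phase, p53 targets and the interferon response. The rest are inflammatory and senescence-associated secretion, extracellular matrix, myofibroblast genes, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, histones, immediate early genes, heat shock, and markers of fibroblasts, epithelium, endothelium, leukocytes and melanocytes. KLF9 is in none of them. A list's median log2 fold change is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. For the knockdown, limma's camera (3.58.1) was run with an inter-gene correlation of 0.01 and with an estimated one, and adjusted over the 27 lists. With an estimated correlation the test rests on 1 residual degree of freedom. It could then hardly call any list, so it is no check of the preset correlation.

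Named genes are KLF9, ITPR1 and TMEM38B, and up to 10 genes per direction and comparison. These have the largest changes among genes with a mean of at least 5 CPM, ranked for the knockdown by the smaller of the 2 hairpins' changes. Up to 4 members of a list with a mean of at least 1 CPM are named too. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other scaling factors (DESeq2 size factors and library totals), other filters and prior counts, DESeq2 1.42.0 as the tool, other controls, and leaving out either hairpin. Leaving out genes that follow epithelial markers was added after seeing the data.

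The methods were tested on simulated counts for the knockdown comparison over 15177 genes. With the dispersion of these data, edgeR called 87% of the genes changed 4-fold, 100% of those changed 16-fold and 5 unchanged genes. The rule of size was passed by 683 unchanged genes, and with a low dispersion by 38. Simulated genes had no spread of their own beyond the fitted dispersion, so these rates do not carry over to the real fit. In that fit KLF9, 12.98-fold lower with hairpin 1 and 6.01-fold lower with hairpin 2, was not called. Of 20 random lists that had been shifted 20 lay above the middle 95% of matched lists, and of 20 that had not, 0 lay above and 1 below.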

Results

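Gene expression was measured by RNA sequencing in 5 libraries of WI38, a line of human lung fibroblasts. The cells carried a KLF9 cDNA, an empty vector, a control shRNA, or 1 of 2 independent shRNAs against KLF9 (hairpin 1 and hairpin 2). KLF9 is a Krüppel-like zinc finger transcription factor, and the study places it in the unfolded protein response, the reaction of cells to misfolded protein in the endoplasmic reticulum (ER). Total counts were 25958350 with control shRNA, 23227588 with hairpin 1, 27241974 with hairpin 2, 23438595 with empty vector and 22859081 with KLF9 cDNA. Each of the 5 was a single library, so no value below has a replicate check beyond the comparison of the 2 hairpins.

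KLF9 was measured first, as a check of the labels. It stood at 354.6 CPM (95% counting interval 347.4 to 361.9) in the library labelled control shRNA, at 27.3 CPM with hairpin 1 (25.2 to 29.5) and at 59.0 CPM with hairpin 2 (56.2 to 61.8). It was 12.98-fold lower with hairpin 1 (11.97 to 14.1) and 6.01-fold lower with hairpin 2 (5.71 to 6.33) than in the library labelled control shRNA. KLF9 cDNA gave 469.5 CPM against 28.2 CPM with empty vector, a 16.6-fold difference (15.4 to 18.1). The 2 controls did not share a baseline: KLF9 was 12.57-fold higher (11.6 to 13.64) in the library labelled control shRNA than with empty vector, and the KLF9 cDNA library exceeded it 1.32-fold (1.29 to 1.36). Hairpin 1 was at 0.968 of the empty vector's level (0.866 to 1.08), within counting error, and hairpin 2 was 2.09-fold above it (1.91 to 2.29). The knockdown was therefore a comparison with a library high in KLF9.

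**Figure D1:**
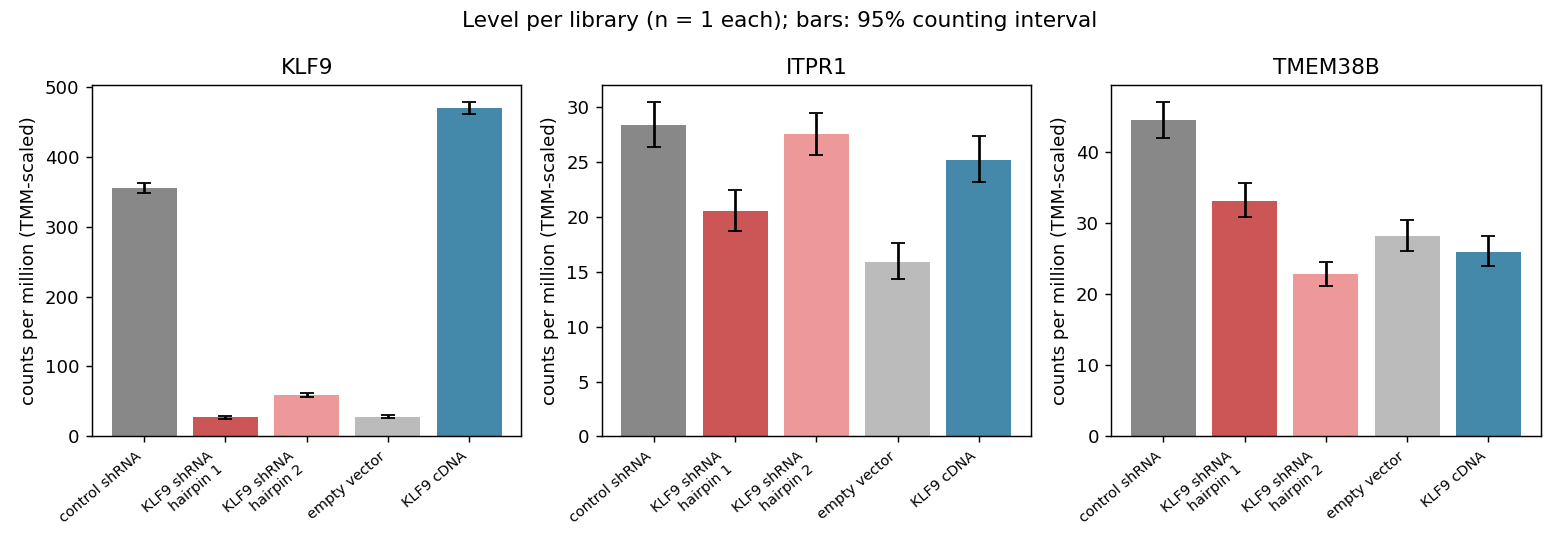
Level of KLF9, ITPR1 and TMEM38B in each of the 5 libraries, in TMM-scaled CPM on a linear axis, with 95% Poisson counting intervals as error bars. KLF9 is at 354.6 CPM in the library labelled control shRNA and 469.5 CPM with KLF9 cDNA, and between 27.3 and 59.0 CPM in the other libraries.

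ITPR1, an ER calcium release channel, and TMEM38B, an ER cation channel that acts in calcium release, were followed as genes of ER calcium handling. ITPR1 was at 28.4 CPM in the library labelled control shRNA, 20.6 CPM with hairpin 1 and 27.5 CPM with hairpin 2. Its log2 change was −0.47 with hairpin 1 (−0.64 to −0.30) and −0.05 with hairpin 2 (−0.19 to 0.10), so that the hairpins did not share a difference beyond counting error. With KLF9 cDNA ITPR1 was 1.58-fold higher than with empty vector (1.39 to 1.82). It was also higher than with empty vector with hairpin 1 (1.29-fold, 1.12 to 1.485) and hairpin 2 (1.73-fold, 1.53 to 1.96). This difference from empty vector is therefore not particular to KLF9 cDNA. TMEM38B was 1.34-fold lower with hairpin 1 (1.22 to 1.47) and 1.95-fold lower with hairpin 2 (1.77 to 2.15), while KLF9 cDNA stood at a log2 change of −0.12 against empty vector (−0.28 to 0.05), within counting error. The library labelled control shRNA was 1.79-fold above empty vector for ITPR1 (1.57 to 2.03) and 1.58-fold above it for TMEM38B (1.43 to 1.74). Against empty vector TMEM38B was at a log2 change of 0.23 with hairpin 1 (0.08 to 0.39) and −0.31 with hairpin 2 (−0.47 to −0.15), so its lower level with both hairpins depends on the control. Neither gene passed edgeR in the knockdown (adjusted p = 1).

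Knockdown of KLF9 was compared with the library labelled control shRNA, itself high in KLF9. Several secreted mediators of inflammation were lower with both hairpins. IL6, a cytokine, was at 252.2 CPM in that library, 67.3 CPM with hairpin 1 and 61.3 CPM with hairpin 2, a mean log2 change of −1.97 ± 0.10 (SD, n = 2). The chemokine CXCL8 was at 1228, 199.8 and 451.2 CPM (−2.03 ± 0.83), and PTGS2, the inducible cyclooxygenase, at 169.9, 34.9 and 57.7 CPM (−1.92 ± 0.51). IL24 (−2.14 ± 0.22), the chemokines CXCL2 (−1.97 ± 0.66) and CXCL10 (−1.72 ± 0.36), and the cytokine IL1A (−1.62 ± 0.23) were lower as well, with KLF9 itself at −3.14 ± 0.78. The remaining named lower genes were POU2F2, a transcription factor, at −2.16 ± 0.21, and the ribosomal pseudogene RPLP0P2 at −2.02 ± 0.49, whose reads may be shared with its parent gene. Of the 26 measured members of the inflammatory and senescence-associated secretion list, 17 were lower with both hairpins and 10 at least 2-fold lower, among them CCL20, CSF2 and MMP3. The 10 include CSF3, which was below 1 CPM in the library labelled control shRNA and with both hairpins. With hairpin 2, 9 of the 26 were higher, 3 of them at least 2-fold. The list was lower as a set in camera (adjusted p = 3.01e-10), with adjusted p = 0.722 under an estimated correlation. That 0.722, the same for every list, comes from a test on 1 residual degree of freedom and decides nothing about the correlation. With both controls as 1 group the list turned to higher and was not called (camera adjusted p = 0.0831). Of its members 8 passed edgeR adjusted over the list alone, and 0 over all genes.

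Genes higher with both hairpins than in the library labelled control shRNA included matrix and pigment genes. TYRP1, an enzyme of melanin synthesis, was at 2.02 CPM there, 12 CPM with hairpin 1 and 8.80 CPM with hairpin 2, a mean log2 change of 2.30 ± 0.31 (SD, n = 2). COL3A1, a fibrillar collagen, was at 622.8, 1293 and 2632 CPM (1.57 ± 0.72). ADAMTS8, a secreted metalloproteinase, differed by 1.77 ± 0.97, PODN, a matrix proteoglycan, by 1.74 ± 0.80, and SCUBE3, a secreted glycoprotein, by 1.10 ± 0.07. WNT2, a secreted signalling protein, differed by 2.72 ± 2.37, ENTPD1, which degrades extracellular ATP, by 2.12 ± 1.48, and WISP1, a matricellular protein, by 1.99 ± 1.16, most of it in hairpin 2. TMEM130 (1.20 ± 0.03) and the sodium channel gene SCN3A (1.13 ± 0.06) complete the named genes. Against empty vector 6 of these 10 genes were higher with both hairpins. TMEM130 and WNT2 were lower there on average, while COL3A1 had a mean of 0.30 (−0.21 with hairpin 1) and ADAMTS8 one of 0.38 (−0.31 with hairpin 1). Of the 27 extracellular matrix genes 21 were higher with both hairpins and 0 lower with both (camera adjusted p = 4.84e-09, and 0.722 with an estimated correlation), with DCN at 0.86 and 1.71 and FBLN1 at 0.76 and 1.45 (log2, hairpins 1 and 2). Over empty vector the list's medians were −0.16 and −0.12. Fibroblast markers, which include some of the same collagens, were called higher (10 of 12 with both hairpins, adjusted p = 1.1e-05, and 0.722 with an estimated correlation), as were melanocyte markers (6 of 8, adjusted p = 2.23e-07, and 0.722), led by TYRP1 and PMEL (1.47 and 1.30). Of their members TYRP1 alone passed edgeR adjusted over the list alone, and 0 over all genes. With both controls as 1 group melanocyte markers were still called higher (0.000318), and extracellular matrix (0.058) and fibroblast markers (0.0831) were not called. Over empty vector alone, however, the melanocyte medians with hairpins 1 and 2 were 0.22 and 0.63. These lay near the middle of matched random lists (percentiles 44.4 and 49.1). Over the library labelled control shRNA the melanocyte medians were 1.38 and 1.18 (percentiles 100 and 94.0). Fibroblast markers had medians of −0.41 and 0.27 over empty vector.

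The interferon response, a program of antiviral genes, was lower with both hairpins than in the library labelled control shRNA in 25 of 28 members (camera adjusted p = 1.17e-10, and 0.722 with an estimated correlation), with list medians of −0.37 and −1.08 for hairpins 1 and 2. RSAD2 (−1.14 and −2.41), IFI27 (−0.86 and −2.19) and CMPK2 (−0.71 and −1.87) had the largest values. Targets of PERK, ATF4 and CHOP, the arm of the unfolded protein response tied to translation control and cell death, had medians of −0.29 and −0.31, with 18 of 28 lower with both hairpins (adjusted p = 1.23e-05, and 0.722 with an estimated correlation). CTH, an enzyme of cysteine synthesis, was at −1.40 and −1.08, and DDIT3, which encodes CHOP, at −0.89 and −1.22. Lower calls, each at 0.722 with an estimated correlation, were also made for histones (11 of 14 lower with both, adjusted p = 2.19e-05), NRF2 antioxidant genes (13 of 26, 0.00513), p53 targets (13 of 22, 0.0118), heat shock genes (9 of 14, 0.015), ERAD and translocation genes (18 of 25, 0.0172), oxidative phosphorylation (17 of 26, 0.0172) and immediate early genes (10 of 18, 0.0172). Higher calls, again at 0.722 with an estimated correlation, were made for G2 and M phase genes (19 of 28 higher with both, adjusted p = 0.00401), with medians of 0.16 and 0.29, and for epithelial markers (8 of 8, adjusted p = 0.00103). The epithelial medians were 0.33 in hairpin 1 and 2.38 in hairpin 2. Of the members of these lists 0 passed edgeR. With both controls as 1 group 5 of them turned to higher and were not called: interferon (0.414), PERK, ATF4 and CHOP (0.856), histones (0.0942), ERAD (0.98) and immediate early genes (0.727). There p53 targets were called higher (0.0149) and G2 and M phase genes lower (7.8e-07), the reverse of the calls above. NRF2 (0.111) and heat shock genes (0.058) were not called, while oxidative phosphorylation (5.57e-06) and epithelial markers (7.8e-07) kept direction and call.

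ER chaperones and folding genes, the textbook targets of XBP1 and ATF6, were not called (12 of 21 lower with both hairpins, camera adjusted p = 0.0535). DNAJB9 was at −0.64 and −0.62, XBP1 at −0.35 and −0.37, and HSPA5, the main ER chaperone, at −0.31 and −0.35. ER calcium handling was not called either (adjusted p = 0.516), and its median with hairpin 1 of 0.00 changed sign with the scaling. Adjusted p-values in camera were 0.0523 for S phase, 0.136 for apoptosis, 0.0899 for cholesterol synthesis, 0.309 for glycolysis and hypoxia, 0.24 for myofibroblast genes, 0.128 for ribosomal proteins, 0.393 for glucocorticoid and circadian genes, the KLF and SP family and endothelial markers, and 0.549 for leukocyte markers. With both controls as 1 group S phase (0.000155), cholesterol synthesis (7.8e-07) and ribosomal proteins (0.000155) were called lower. The medians of the KLF and SP family changed sign with the scaling in both hairpins, as did those of ribosomal proteins in hairpin 1 and of glucocorticoid and circadian genes in hairpin 2. Hairpin 2's median and the test's direction differed in sign for myofibroblast genes (−0.34, test higher) and leukocyte markers (0.40, test lower), and hairpin 1's did for cholesterol synthesis (0.05, test lower) and glycolysis (0.07, test lower).

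**Figure D2:**
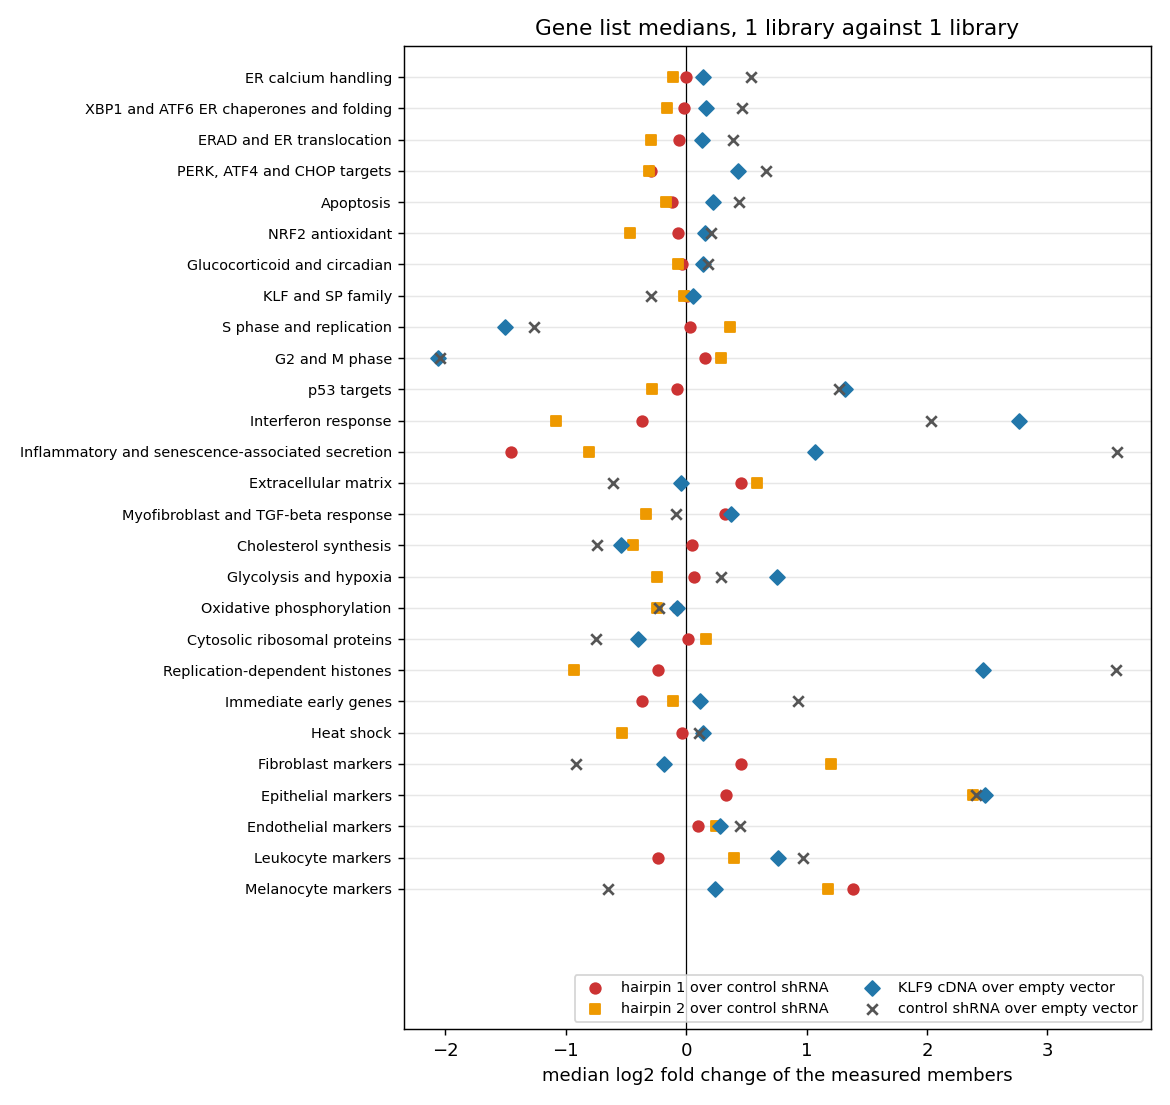
Median log2 fold change of the measured members of each of 27 gene lists, for 4 comparisons of 1 library with 1 library. Points to the right of the zero line are higher in the library named first. G2 and M phase genes have medians of −2.06 with KLF9 cDNA over empty vector and −2.04 with the library labelled control shRNA over empty vector, and 0.16 and 0.29 with the hairpins over that library.

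No gene passed edgeR's quasi-likelihood test for the knockdown (0 of 15177, smallest adjusted p = 1), KLF9 included. At an unadjusted p under 0.05 there were 186 genes, 102 higher and 84 lower, against 758.8 that chance gives. DESeq2 called 2 genes, both lower: KLF9 (log2 change −3.02, SE 0.459, adjusted p = 7.1e-07) and IL6 (−1.96, SE 0.37, adjusted p = 0.000935), with 215 genes at an unadjusted p under 0.05, and edgeR without its filter on low counts called 78. By size, 88 of 13205 genes changed at least 2-fold in the same direction in both hairpins, 46 higher and 42 lower. Hairpin 1 alone gave 152 (51 higher, 101 lower) and hairpin 2 alone 1479 (1049 higher, 430 lower). Independent lists would share 4.05 higher and 3.29 lower genes, but both comparisons use 1 control library. Simulated unchanged libraries against 1 control shared on average 226 higher and 153 lower genes with the dispersion of these data, and 0.3 and 0.05 with counting error alone. Across genes, which are not independent replicates, the hairpins' changes had a Pearson correlation of 0.401 (Spearman 0.356) and a covariance of 0.131. The simulations gave 0.5 and 0.245 with the dispersion of these data, and 0.496 and 0.0261 with counting error alone. The observed sharing thus lay below what a common control gives with the dispersion of these data. Its counts and covariance lay above what it gives with counting error alone. That dispersion comes only from the difference between the 2 hairpins. Hairpin 1 was closer to the library labelled control shRNA (correlation 0.9909) than to hairpin 2 (0.9686). The dispersion may therefore be too large for unchanged libraries, and the simulation cannot decide whether the sharing exceeds that of a common control.

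Overexpression of KLF9 was read from the KLF9 cDNA library against the empty vector library. Interferon-response genes led the increases: RSAD2, an antiviral enzyme, was at 189.1 CPM against 7.34 CPM, a log2 difference of 4.67 (95% counting interval 4.46 to 4.92), with IFI27 at 4.10 (3.61 to 4.86), IFIT2 at 3.88 (3.76 to 4.0), MX1 at 3.69 (3.60 to 3.78) and IFI6 at 3.55 (3.48 to 3.63). CXCL10, an interferon-inducible chemokine, was at 3.93 (3.53 to 4.48) and BATF2, an interferon-inducible transcription factor, at 3.76 (3.49 to 4.10). KLF9 itself was at 4.05. Of 28 measured interferon-response members 25 were at least 2-fold higher and 0 lower by that much, with a list median of 2.76 at percentile 100 of matched random lists. The other libraries were above empty vector as well, with medians of 2.04 in the library labelled control shRNA, 1.59 with hairpin 1 and 0.79 with hairpin 2. KRT19, an epithelial keratin, was 3.68 higher (3.16 to 4.48), together with the epithelial marker list (7 of 8 at least 2-fold higher, median 2.48, against 2.41, 2.69 and 4.88 in the other libraries in the same order). HIST1H2AC, a histone gene of a multigene family, was 3.55 higher (3.16 to 4.07), and 12 of 14 measured histone genes were at least 2-fold higher (median 2.46, the smallest of the 4, with 3.57, 3.40 and 2.76 in the others).

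The genes lowest with KLF9 cDNA against empty vector were dominated by genes of chromosome segregation and cell division. CENPF, a kinetochore protein, was at 52.1 CPM against 288.8 CPM (log2 difference −2.47, −2.56 to −2.38). DLGAP5 (−2.52), CEP55 (−2.48), ITGB3BP (−2.45), DEPDC1 (−2.45), NUF2 (−2.43) and ASPM (−2.39), which act in the spindle, the centromere or cytokinesis, lay close to it. The same set held FAM111B (−2.58), LMNB1, a nuclear lamin (−2.40), and ESCO2, which acts in sister chromatid cohesion (−2.39). All 28 G2 and M phase genes were at least 2-fold lower (median −2.06, percentile 0), as were 27 of 29 S phase genes (median −1.51, percentile 0). p53 targets had a median of 1.32 (percentile 100), with 14 of 22 at least 2-fold higher, and CDKN1A, a cyclin-dependent kinase inhibitor, was at 2056 CPM against 361.1 CPM. The empty vector library stood apart from all the others in these lists. Against it the G2 and M phase medians were −2.04 in the library labelled control shRNA, −1.89 with hairpin 1 and −1.81 with hairpin 2, and those of p53 targets 1.27, 1.15 and 1.11. KLF9 cDNA against the library labelled control shRNA had a G2 and M phase median of 0.10.

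Among genes of ER stress, targets of PERK, ATF4 and CHOP had a median of 0.43 with KLF9 cDNA (percentile 100), with 7 of 28 at least 2-fold higher and 0 lower by that much. The other libraries stood above empty vector too, with medians of 0.66 in the library labelled control shRNA, 0.38 with hairpin 1 and 0.56 with hairpin 2. ATF3, a stress-induced transcription factor, was at 2.61, CTH at 2.28, SESN2 at 1.61 and DDIT3 at 1.5. ER chaperones had a median of 0.16 (percentile 91.5), with DNAJB9 at 1.23 and XBP1 at 0.73. ER calcium handling (median 0.14, percentile 87.6), ERAD and translocation (0.13, 87.4), apoptosis (0.22, 97.0) and NRF2 genes (0.16, 91.0) lay within the middle 95% of random lists. Inflammatory and secreted genes had a median of 1.07 (percentile 100), with 13 of 26 at least 2-fold higher, including MMP3 at 3.48 and IGFBP3 at 2.61, and the other libraries had larger medians (3.57, 1.71 and 2.68 in the same order). Glycolysis and hypoxia genes were higher in 23 of 23 members (median 0.76, percentile 100), myofibroblast genes had a median of 0.37 (percentile 99.8), cholesterol synthesis −0.54 and ribosomal proteins −0.40 (both percentile 0). In the other libraries, in the same order, cholesterol synthesis was at −0.74, −0.68 and −1.16 and ribosomal proteins at −0.75, −0.70 and −0.58, so these 2 differences are not particular to KLF9 cDNA. Glycolysis was at 0.29, 0.29 and −0.20 and myofibroblast genes at −0.09, 0.29 and −0.31. The lists of extracellular matrix (−0.04), oxidative phosphorylation (−0.08), the KLF and SP family (0.06), glucocorticoid and circadian genes (0.14), immediate early genes (0.11), heat shock (0.14), and fibroblast (−0.18), endothelial (0.28), leukocyte (0.76) and melanocyte (0.24) markers lay within the middle 95%.

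By size, 1279 of 12675 genes (10.1%) differed at least 2-fold between KLF9 cDNA and empty vector, 687 higher and 592 lower. The excess of higher genes depended on the genes counted. At a mean of 5 CPM there were 368 higher and 470 lower, and with no CPM filter 2218 and 1041. Without the genes that follow epithelial markers, a choice that by construction takes out higher genes, there were 563 and 592. With the library labelled control shRNA as the control there were 621, and 87 passed against both controls in the same direction. With the spread borrowed from the hairpins, edgeR called 0 genes (smallest adjusted p = 0.072, 1266 at an unadjusted p under 0.05). The difference of 1 library from 1 library has no replicate check.

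The study's design pairs loss and gain of KLF9, so the 2 sets of changes were set side by side. Of 12529 genes measured in both, 20 were at least 2-fold lower with both hairpins and 2-fold higher with KLF9 cDNA, against 1.45 for independent lists, and 0 were lower in both against 1.2. Genes higher with both hairpins were lower with KLF9 cDNA in 4 cases and higher in 4, against 1.11 and 1.34. At 1.5-fold the counts were 74 lower then higher (15.1 for independent lists), 7 lower in both (15.5), 49 higher then lower (18.5) and 30 higher in both (18.0). Named genes of the lower then higher kind were KLF9, IL6, PTGS2, CXCL2, IL1A, CXCL10, MMP3, a matrix metalloproteinase, CXCL8, IL24 and RSAD2. For IL6 the change was −1.90 and −2.04 with the hairpins and 2.41 with KLF9 cDNA, and for MMP3 −1.54, −1.27 and 3.48. Named genes of the higher then lower kind were ADAMTS15, CCL11, WNT2, IL16, ADH1B, OLFML2A, PLXNC1, COL14A1, TOX and SCN7A. CCL11, a chemokine, was at 1.60 and 3.93 with the hairpins and −1.12 with KLF9 cDNA, and ADH1B, an alcohol dehydrogenase, at 0.96, 3.86 and −2.38. Across 15177 genes the mean change of the hairpins and that of KLF9 cDNA had a Pearson correlation of 0.024 and a Spearman correlation of −0.159.

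All 10 lower then higher genes were also at least 2-fold higher in the library labelled control shRNA than with empty vector (log2 differences of 2.80 to 7.04), and 9 of the 10 higher then lower genes were at least 2-fold lower there. IL6 was at 9.06 CPM with empty vector and 48.4 CPM with KLF9 cDNA, both below the hairpin libraries. The opposite changes thus involve 2 controls that differ from each other. With the controls exchanged 227 genes moved opposite ways in place of 24.

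**Figure D3:**
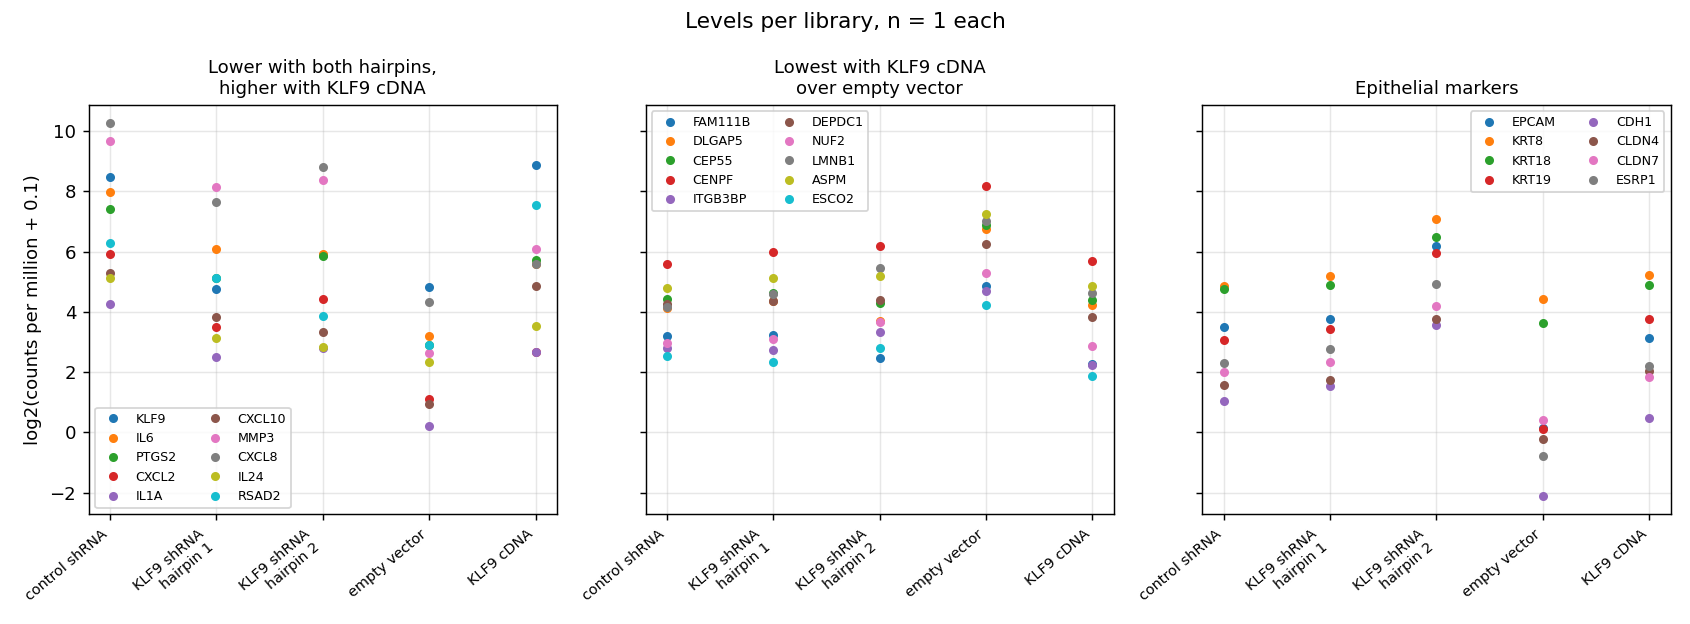
Level of each named gene in each of the 5 libraries as log2(CPM + 0.1), for genes lower with both hairpins and higher with KLF9 cDNA, for the genes lowest with KLF9 cDNA against empty vector, and for epithelial markers. Each cell division gene is highest in the empty vector library, with CENPF at 288.8 CPM there and 52.1 CPM with KLF9 cDNA, and EPCAM is at 73.7 CPM in hairpin 2 and 1.02 CPM with empty vector.

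The 2 control libraries were compared as a background. Their labels name a control shRNA and an empty vector, and do not say whether they differ in anything else. By size 1950 of 12747 genes (15.3%) differed between them, 980 higher and 970 lower with empty vector, more than the 1279 between KLF9 cDNA and empty vector. With the spread borrowed from the hairpins, edgeR called 97 genes between these controls (44 higher and 53 lower with empty vector, smallest adjusted p = 0.0149, 2055 at an unadjusted p under 0.05). That is 1 library against 1 with a spread not their own, so the calls describe these 2 libraries and add no replicate check to the counts by size. Scaled by library totals the split was 845 higher and 1090 lower. Hairpin 2 differed from hairpin 1 in 1382 of 13285 genes (1065 higher, 317 lower). Epithelial markers took part in several of these differences: EPCAM, a surface protein of epithelial cells, was at 11.1 CPM in the library labelled control shRNA, 13.4 CPM with hairpin 1, 73.7 CPM with hairpin 2, 1.02 CPM with empty vector and 8.69 CPM with KLF9 cDNA. Genes with such a profile over the 5 libraries (correlation with the epithelial markers of at least 0.95 and a log2 range of at least 2) made up 404 of the 1049 genes higher with hairpin 2, 124 of the 687 higher with KLF9 cDNA and 12 of the 46 higher with both hairpins. Without them the counts were 645, 563 and 34. The profile itself is highest with hairpin 2 and lowest with empty vector, so genes chosen by it are higher in these comparisons by construction, and the counts do not show where their signal comes from.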

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

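Scaling and the prior count were run on 72 fold changes, those of the genes named for their size or for opposite changes and of KLF9, ITPR1 and TMEM38B, and turned none. Leaving out a hairpin could not turn the genes chosen for agreeing in both, so it says nothing of their stability. Genes named as members of lists were not run. The choice of control decided most directions. No paired analysis was possible because the groups compared share no more than 1 replicate number. Leaving out genes that follow epithelial markers was chosen after seeing the data and left 76, 1155, 24 and 1824 genes in the counts of 88, 1279, 24 and 1950. The profile peaks in hairpin 2 and is lowest with empty vector, so by construction it took higher genes from the knockdown (46 to 34) and the overexpression (687 to 563), and genes lower with empty vector from the comparison of controls (970 to 844). Where no reason is given, the cause was not tested.

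Both hairpins against empty vector in place of the library labelled control shRNA turned the mean log2 change of 23 genes. It became 0.51 for KLF9, 0.58 for ITPR1, 0.89 for POU2F2, 0.66 for IL24, 2.81 for IL6, 1.56 for RPLP0P2, 2.60 for PTGS2, 2.84 for CXCL2, 2.46 for IL1A, 2.66 for CXCL10, 3.90 for CXCL8, 5.64 for MMP3 and 1.61 for RSAD2. It became −0.89 for TMEM130, −0.88 for WNT2, −1.87 for ADAMTS15, −1.55 for CCL11, −0.25 for IL16, −2.34 for ADH1B, −2.19 for OLFML2A, −2.64 for PLXNC1, −1.66 for TOX and −1.31 for SCN7A. KLF9 cDNA against the library labelled control shRNA turned 24 genes. These were CXCL10 (−0.45), IFI6 (−0.26), HIST1H2AC (−0.77), IL6 (−2.38), PTGS2 (−1.68), CXCL2 (−3.26), IL1A (−1.61), MMP3 (−3.56), CXCL8 (−4.67), IL24 (−1.60) and ITPR1 (−0.17), and in the other direction DLGAP5 (0.12), CENPF (0.11), LMNB1 (0.46), ASPM (0.075), ADAMTS15 (2.11), CCL11 (3.20), WNT2 (1.80), IL16 (0.70), ADH1B (2.36), OLFML2A (2.42), PLXNC1 (2.30), TOX (1.86) and SCN7A (1.05). The construction shows the reason: the 2 control libraries differ in these genes. Without a turn, the mean over the hairpins against empty vector shrank to 0.30 for COL3A1, 0.38 for ADAMTS8 and −0.04 for TMEM38B. TYRP1 became smaller too, at 1.59 and 1.14 with hairpins 1 and 2. SCUBE3 (3.10 and 3.20) and SCN3A (1.35 and 1.44) became larger.

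The 88 knockdown genes by size became 519 with no CPM filter and 30 at a mean of 5 CPM. Leaving out a hairpin gave 152 to 1479, with 152 from hairpin 1 alone and 1479 from hairpin 2 alone. With hairpin 1 against the library labelled control shRNA and hairpin 2 against empty vector there were 28, in the reverse arrangement 429, and with both against empty vector 1247. The 1279 overexpression genes became 3259 with no CPM filter (2218 higher, 1041 lower), 838 at a mean of 5 CPM (368 higher, 470 lower), 621 with the library labelled control shRNA as the control and 87 against both controls. By edgeR with the borrowed spread there were 0, and 0 against both controls as 1 group, with 1266 and 96 at an unadjusted p under 0.05. The 24 genes moving opposite ways became 11 at a mean of 5 CPM, 123 at 1.5-fold and 227 with the controls exchanged, and 34 to 248 on leaving out a hairpin, 248 being without hairpin 1.

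The 0 knockdown genes called by edgeR stayed 0 with DESeq2's size factors, a mean of 5 CPM, the 3 shRNA libraries alone and both controls as 1 group. DESeq2 called 2. Without the filter on low counts edgeR called 78 (63 higher), all 78 among the 15177 genes of the filtered test. The prior degrees of freedom were then infinite against 6.36, so that each gene's own spread no longer counted. With library totals KLF9 in hairpin 2 stood at a log2 change of −2.49 in place of −2.59. The 15 gene lists called by camera became 0 with an estimated correlation. That test rests on 1 residual degree of freedom and could hardly call any list. Extracellular matrix had an estimated correlation of −0.00285, below the preset 0.01, yet its unadjusted camera p rose from 5.38e-10 to 0.0907. Among called lists, only PERK, ATF4 and CHOP targets (−0.0317) also had an estimate below the preset value. The others lay above it, with interferon at 0.725, histones at 0.714 and inflammatory genes at 0.354. These estimates rest on 1 residual degree of freedom as well, but the preset value may be too low for such lists. With both controls as 1 group 8 lists were called. Of the 15, 8 turned direction there and 10 were no longer called. G2 and M phase genes turned to lower (limma camera adjusted p = 7.8e-07) and p53 targets to higher (0.0149), both still called. Inflammatory (0.0831), interferon (0.414), PERK, ATF4 and CHOP (0.856), histone (0.0942), ERAD (0.98) and immediate early genes (0.727) turned to higher without a call. Extracellular matrix (0.058), fibroblast (0.0831), NRF2 (0.111) and heat shock genes (0.058) kept their direction without a call. Oxidative phosphorylation, epithelial and melanocyte markers kept direction and call, and S phase, cholesterol synthesis and ribosomal proteins were newly called, all 3 lower. Lists outside the middle 95% of random lists in both hairpins numbered 9, and 13 to 16 in 1 hairpin alone. A gene's own counts set the width of its interval: POU2F2, at 1.33 CPM with empty vector and 2.61 CPM with KLF9 cDNA, had a log2 interval of 0.31 to 1.66, against 3.94 to 4.17 for KLF9.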

Other observations

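The gene lists and the count of 621 genes below were set before the data were examined, and the other tests reported here were chosen after the values had been seen. The KLF9 cDNA library and the library labelled control shRNA, which had KLF9 levels within 1.32-fold of each other, differed at least 2-fold in 621 of 12902 genes. Inflammatory and secreted genes were at least 2-fold lower with KLF9 cDNA in 19 of 26 members (median −2.06, percentile 0 of matched random lists), with CXCL8 at 48.1 CPM against 1228 CPM and MMP3 at 68.8 CPM against 813.8 CPM. Immediate early genes (median −0.67), histones (−0.77) and targets of PERK, ATF4 and CHOP (−0.35) were lower too, each at percentile 0. Glycolysis and hypoxia genes (0.62), interferon-response genes (0.74) and extracellular matrix genes (0.45) were higher, each at percentile 100. G2 and M phase genes had a median of 0.10 (percentile 93.5), and p53 targets one of 0.01 whose sign changed with the scaling.

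Set against empty vector, the changes of KLF9 cDNA across 15177 genes, which are not independent replicates, had a Pearson correlation of 0.803 with those of the library labelled control shRNA, 0.821 with those of hairpin 1 and 0.693 with those of hairpin 2. Simulated unchanged libraries that share the empty vector library gave 0.502, 0.5 and 0.504 with the dispersion of these data. The covariances were 0.631, 0.597 and 0.686, against 0.237, 0.234 and 0.247 simulated. The glucocorticoid and circadian list and the KLF and SP family were not called in the knockdown (camera adjusted p = 0.393 each), and 8 of their 37 measured members were higher in both libraries with high KLF9 than in the other 3. The share of all tested genes with that pattern was not counted, so the 8 cannot be read as an excess. The genes that follow were picked for their values. NR1D1, a clock repressor, was at 86.0 CPM with the label control shRNA, 61.8 and 50.4 CPM with hairpins 1 and 2, 20.7 CPM with empty vector and 91.5 CPM with KLF9 cDNA. KLF15, a related factor, was at 5.22, 2.27, 2.71, 0.619 and 5.26 CPM in the same order. DBP, a clock output factor, went the other way only against each library's own control. Its log2 changes were 0.33 and 1.02 with the hairpins and −1.34 with KLF9 cDNA. By level it was at 2.1, 2.66, 4.33, 8.45 and 3.29 CPM in the same order, so KLF9 cDNA lay above hairpin 1.

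The first pattern weighed is the high KLF9 level in the library labelled control shRNA. If only 1 library was meant to be high, an exchange of labels among these 5 would not account for 2 high ones. The second highest KLF9 level was 6.013-fold above the third highest, and 2 libraries stay high under any assignment. That ratio is the same for every assignment, so it cannot show whether labels were exchanged. An exchange with a library outside the series stays open. A raised unfolded protein response may have raised the endogenous gene. The ER chaperone list had a median of 0.47 in the library labelled control shRNA over empty vector (percentile 99.95), although 19 of 27 lists lay outside the middle 95% there. Of its 21 members 13 were higher and 8 lower, with HSP90B1 (1237 against 1440 CPM) and CALR (1012 against 1191 CPM) among the lower. Over empty vector, PERK, ATF4 and CHOP targets were higher in that library in 24 of 28 members (median 0.66, percentile 100). ERAD and translocation genes were higher in 21 of 25 (median 0.39, percentile 99.95). Hairpins 1 and 2, low in KLF9, also had chaperone medians above empty vector (percentiles 96.94 and 99.78). The hairpins are directed against KLF9 itself, so their values do not decide on this explanation. KLF9 cDNA carried by the shRNA cells cannot be told apart from the endogenous gene, because gene totals do not separate them, and the cDNA library's level was 1.324-fold higher.

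The second pattern is the distance of the empty vector library from the other 4 in cell division, interferon and p53 genes. If the KLF9 level at harvest set these genes, both hairpin libraries were predicted to lie within 0.5 (log2) of empty vector. Hairpin 1, at 0.968 of the empty vector's KLF9 level, had a G2 and M phase median of −1.89 (95% interval over the member genes −2.01 to −1.78). Its medians for interferon (1.59, 1.41 to 1.77) and p53 targets (1.15, 0.74 to 1.5) lay beyond 0.5 as well. Hairpin 2, nearer to empty vector, had −1.814 (−2.01 to −1.56), 0.7925 (0.59 to 1.16) and 1.111 (0.661 to 1.18) in the same order. Its KLF9 was 2.09-fold above empty vector, so the limit of 0.5 need not hold there. These intervals take the genes of a list as independent, which they are not, and hold no spread between cultures. As values of 1 library, the medians of hairpin 1 argue against the KLF9 level at harvest as the whole cause. An earlier effect of KLF9 that outlasts its loss, or a partial one, stays open. The growth state or handling of the empty vector culture could account for it as well and cannot be told apart from KLF9: the only other control, with a G2 and M phase median of −2.042, is high in KLF9.

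The third pattern is the epithelial transcripts in hairpin 2. Fibroblasts should hold few of them, and KRT8 was at 137.1 CPM, KRT18 at 89.8 CPM, EPCAM at 73.7 CPM and KRT19 at 61.7 CPM there, against 21.4, 12.2, 1.02 and 0.973 CPM with empty vector, while the fibroblast markers were not lower: 10 of 12 were higher than in the library labelled control shRNA (median 1.21, COL1A1 at 6232 CPM against 2822 CPM), with VIM, at 2589 CPM against 4464 CPM, among the 2 lower. Material from an epithelial source is a candidate explanation: in a second list, written after several of its genes had been seen, 18 of 18 were at least 2-fold higher than in the library labelled control shRNA, by a median of 2.57 (SD 0.446). CDKN2A, chosen after its values were seen, followed the same profile with 1001 counts against 145. KLF9 knockdown is argued against by hairpin 1, which had the lower KLF9 level and an epithelial median of 0.3348 (range 0.143 to 0.487). An effect of hairpin 2 alone was not tested, and cells cannot be separated from reads carried over between libraries here.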
